A study of Mus musculus with 18 samples.

How the data were processed

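RNA-seq was made from bone marrow-derived macrophages of C57BL/6J mice, differentiated for 7 days. On day 8 the cells received reconstituted high-density lipoprotein (rHDL, CSL111, made of APOA1 and soybean phosphatidylcholine at a ratio of 1 to 150) for 20 h, were washed, and were then stimulated with lipopolysaccharide (LPS). In some groups the cells were loaded with cholesterol beforehand, with liposomes of phosphatidylcholine and cholesterol. The dose and duration of LPS are not given in the sources used here, nor is it stated whether replicates were separate cultures or animals. Per the labels, RNA had an integrity number above 8 and libraries were made by poly-dT selection.

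Per the labels, the authors trimmed reads with cutadapt, aligned them to mm10 with HISAT2 and counted them with featureCounts of Subread. Versions are not given in the sources used here. The deposited count tables hold raw read counts for 32850 rows, 1 per annotated transcript, with 24059 gene symbols, and the authors did not normalise them. The first table holds 6 libraries (untreated and LPS) and the second holds 12 (LPS, rHDL then LPS, loading then LPS, loading then rHDL then LPS), with 3 libraries per group. The deposited comparison tables hold a log2 fold change and an adjusted p-value that the authors made with DESeq2, and a ratio of RPKM values. Their largest adjusted p was 0.0497 without loading and 0.0475 after loading, and neither lists a ratio between 1/1.5 and 1.5, so both were filtered on these values.

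All 6696 rows with no exon base of their own had 0 counts in the 18 libraries (100.0%), so reads that overlap more than 1 row were left out of the deposited counts. Genes with overlapping transcripts are therefore measured in part or not at all. Hmgcs1 and Ddit3 had few exon bases of their own, so neither is reported. Some other genes that the rule for named genes takes are not reported here. Of the genes named, Tnf had 2.9% of its exon bases to itself, Cd74 13.6% and Mx1 15.6%. No row lies on the mitochondrial chromosome, so the list of mitochondrial transcripts could not be tested.

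Rows were summed per gene symbol and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), which left 9576 genes in the first table and 8965 in the second. Libraries were scaled by TMM. Quasi-likelihood F tests compared the groups, with the 2 tables fitted apart and all 12 libraries of the second sharing 1 fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were LPS against untreated cells, rHDL against none under LPS, the same after loading, the difference between these rHDL effects, and loading against none under LPS. CPM values are counts scaled to library size by TMM. A value after ± is the standard error for a log2 fold change and the SD for a CPM, and n = 3 libraries in every group.

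Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), 2-sided, with a preset inter-gene correlation of 0.01 and, beside it, an estimated correlation. The 31 fixed lists cover lipid metabolism, inflammation, stress, energy metabolism, antigen presentation, cell identity, markers of other cells and control genes, and p was adjusted over the lists of a comparison. Genes called in the first table with a log2 change of at least 1 either way formed an LPS-induced set of 1538 genes and an LPS-repressed set of 1840. These sets come from these samples, but from another table than the one they are tested in.

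Named genes followed a rule. For each comparison it takes the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, passing over predicted genes and clones. It adds up to 4 members of each list with the smallest p, a fixed panel of inflammatory and lipid genes, and the 6 genes with the smallest p for the difference between rHDL effects. The genes printed are a part of those the rule takes, picked after their values were seen, as were list members named only to spell out a small count. The comparisons, tests, lists, this rule and the main alternatives were fixed before the data were examined.

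Alternatives fixed in advance were DESeq2 1.42.0, its size factors, 2 other low-count filters, the replicate number as a block, a minimum of 1.5-fold, fits of 2 groups alone, an estimated correlation, other gene sets and leaving out each library. The 4 added ones were chosen after seeing the data: scaling by library totals only, rows tested singly, genes with 1 row and no shared exon base, and counts thinned to the smallest library. In simulated counts with 100 genes changed by 1.5-fold, edgeR recovered 75 for the LPS comparison, 54 for rHDL, 60 for rHDL after loading, 38 for the difference and 62 for loading. At 2-fold it recovered 85, 84, 85, 72 and 80. Among the unchanged genes it called 8, 7, 4, 3 and 12.

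Depth was 11450243 to 16835472 counts per library in the first table and 9464916 to 15607889 in the second. Chi-square per degree of freedom between replicates ran from 3.0 to 34.7, so replicates varied by more than counting error. Where a group had few counts, the ratio of summed counts is given with a 95% interval or against a floor of 3 counts over the group. Such intervals and floors cover counting error only, since reads carry no molecular identifiers.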

Results

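Gene expression was measured by RNA-seq in 18 libraries of mouse bone marrow-derived macrophages, in 6 groups of 3. Untreated cells and LPS-stimulated cells formed the first experiment table. The second held 4 groups, all stimulated with LPS: no pretreatment, rHDL for 20 h, cholesterol loading, and loading followed by rHDL. Total counts were 11450243 to 16835472 per library in the first table and 9464916 to 15607889 in the second. The LPS groups of the 2 tables are kept apart in every test.

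LPS against untreated cells gives the response to LPS within the first table. Its LPS group differed in level from that of the second table for some genes, such as Il10 (14.3 and 273 CPM), without a test. Il6, an inflammatory cytokine (mm10 chromosome 5, 30013161 to 30019968), rose from 0.395 ± 0.488 to 1891 ± 180 CPM, a log2 fold change of 12.44 ± 0.33 (adjusted p = 1.29e-10). Il12b rose by 10.01 ± 0.13 and Il1b by 10.11 ± 0.38. Ptgs2, the inducible cyclooxygenase, rose by 10.42 ± 0.17, and Nos2, the inducible nitric oxide synthase, by 9.48 ± 0.15. All 16 measured cytokines of the fixed list rose (16 adjusted over the list alone; adjusted p = 3.6e-09, and adjusted p = 0.0845 with an estimated correlation). So did all 16 measured chemokines (16 adjusted over the list alone; adjusted p = 2.01e-09, and adjusted p = 0.164 with an estimated correlation), among them Cxcl1 (8.78 ± 0.17) and Ccl5 (6.83 ± 0.12). All 31 measured interferon response genes rose (31 adjusted over the list alone; adjusted p = 3.25e-15, and adjusted p = 0.362 with an estimated correlation), such as Gbp5 (7.90 ± 0.11) and Rsad2 (6.62 ± 0.15).

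Some induced genes had almost no counts in untreated cells. Csf2 had 2 counts in untreated cells and 4448 with LPS, a ratio of 3567 with a 95% counting interval of 987 to 29464. Il23a went from 1 to 2284 counts, a ratio of 3663 (657 to 144757), and Ifnb1 from 3 to 442, a ratio of 236 (80 to 1150). Tnf went from 7 to 163 counts, a ratio of 37 (18 to 94), and its counts come from the 2.9% of its exon bases that no other transcript row shares.

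Regulators and stress genes moved with LPS as well. All 20 measured NF-kB feedback and Toll-like receptor effector genes rose (20 adjusted over the list alone; adjusted p = 4.34e-11, and adjusted p = 0.0845 with an estimated correlation), including Socs3 (7.88 ± 0.13) and Irg1 (6.71 ± 0.11). All 18 measured genes of the ATF4 stress list rose (18 adjusted over the list alone; adjusted p = 2.14e-08, and adjusted p = 0.185 with an estimated correlation), such as Chac1 (4.02 ± 0.10) and Gdf15 (3.42 ± 0.11). Of 14 inflammasome genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.357 with an estimated correlation). Nlrp3, an inflammasome sensor, rose by 4.49 ± 0.10. Of 14 costimulation and MHC class I genes 13 rose (13 adjusted over the list alone; adjusted p = 2.97e-05, and adjusted p = 0.164 with an estimated correlation). Cd274, a checkpoint ligand, rose by 4.16 ± 0.10. Of 17 genes of the Toll-like receptor machinery, which holds receptors and signalling genes such as Myd88, 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.429 with an estimated correlation). Of 15 anti-inflammatory regulators 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.357 with an estimated correlation).

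Among genes that fell with LPS, Cx3cr1, the fractalkine receptor, went from 139 ± 14.3 to 3.20 ± 1.19 CPM, a log2 change of -5.44 ± 0.19. Cnr2, a cannabinoid receptor, changed by -7.55 ± 0.18 and Cd300lb by -5.88 ± 0.13. Of 22 cell cycle genes 19 fell and 2 rose (19 and 2 adjusted over the list alone; adjusted p = 0.00823, and adjusted p = 0.687 with an estimated correlation). Mcm7 of the replicative helicase fell by 2.39 on the log2 scale, while Mki67, a proliferation marker, rose by 3.67 ± 0.26 and Ccne1 was the other riser. Of 10 fatty acid synthesis genes 8 fell (8 adjusted over the list alone; adjusted p = 0.0464, and adjusted p = 0.685 with an estimated correlation), with Fads1 at -2.38 ± 0.10. The cholesterol synthesis list had 8 members higher and 6 lower (8 and 6 adjusted over the list alone), a median of -0.13, a mean of 0.0025 and no call (adjusted p = 0.884). Cyp51, a sterol demethylase, rose by 0.96 ± 0.08 and Insig1, a regulator of sterol synthesis, by 1.03 ± 0.09, while Dhcr7 changed by -2.79 ± 0.15.

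Of 9576 genes tested with LPS, 3380 were higher and 3605 lower, and 7163 had an unadjusted p under 0.05. Scaling by library totals alone moved the median of all genes to -0.77 and gave 1532 higher and 6640 lower, so 18.7% of calls were higher in place of 48.4%. Under that scaling the medians of 3 of the 14 called lists changed sign: oxidative phosphorylation (0.37, then -0.35; 16 of 22 higher), MHC class II (0.70, then -0.02; 5 of 6 higher) and control genes (0.45, then -0.27; 8 of 9 higher). Their adjusted p were 0.0153, 0.0376 and 0.0259, and adjusted p = 0.722, 0.637 and 0.609 with an estimated correlation. Counts adjusted over the list alone were 16, 5 and 8. These 3 calls ended under that scaling, as did those of the cell cycle and fatty acid synthesis lists. The change of Abca1 (0.56 ± 0.12) became -0.15 and that of Atf3 (0.58 ± 0.09) became -0.13. Among markers of other cells, 2 of 3 neutrophil and 3 of 3 dendritic genes were higher with LPS, and neither list was called (adjusted p = 0.391 and 0.124).

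rHDL before LPS, without cholesterol loading, was compared with LPS and no pretreatment. No group had rHDL without LPS, so a change already present before LPS cannot be told from an altered response to LPS. Abca1, a cholesterol exporter (chromosome 4, 53030789 to 53159895), went from 603 ± 46.8 to 65.0 ± 6.15 CPM, a log2 change of -3.21 ± 0.12 (adjusted p = 8.64e-10). Abcg1, another exporter, changed by -2.62 ± 0.08, while Sqle (1.56 ± 0.12) and Insig1 (1.25 ± 0.07), of the cholesterol synthesis list, rose. Cxcl1, a neutrophil attractant (chromosome 5, 90891245 to 90893115), went from 364 ± 61.0 to 2256 ± 362 CPM (2.63 ± 0.15), and Ccl2, a monocyte attractant, from 176 ± 32.2 to 841 ± 20.3 (2.26 ± 0.16).

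Of 22 cholesterol synthesis genes 21 rose, with a median of 1.29 (21 adjusted over the list alone; adjusted p = 2.21e-12, and adjusted p = 0.058 with an estimated correlation). Of 14 liver X receptor (LXR) targets 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -1.02 (adjusted p = 3.2e-05), and this was the 1 list call of the comparison that held with an estimated correlation (adjusted p = 0.0386). Pltp changed by -1.23 ± 0.06 and Mylip by -1.49 ± 0.09, and the riser was Scd1, a fatty acid desaturase. Of 10 fatty acid synthesis genes 7 rose (7 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.209 with an estimated correlation), such as Fasn (1.64 ± 0.23) and Fads2 (2.92 ± 0.24). Ch25h, which makes 25-hydroxycholesterol, changed by -1.73 ± 0.15, and Plin2, a lipid droplet coat protein, by 0.80 ± 0.08.

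Of 15 cytokines 9 rose and 3 (Ebi3, Il18 and Il27) fell (9 and 3 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.209 with an estimated correlation). Il12b rose from 176 ± 5.77 to 431 ± 15 CPM (1.29 ± 0.09), Il23a by 2.48 ± 0.25, Csf2 by 3.12 ± 0.37 and Il1b by 0.30 ± 0.08. The changes of Il6 (0.18 ± 0.19, adjusted p = 0.493) and of Tnf (0.60 ± 0.27, adjusted p = 0.101) did not pass. Of 17 chemokines 10 rose and 5 (Ccl12, Ccl5, Ccl8, Cxcl10 and Cxcl9) fell (10 and 5 adjusted over the list alone; adjusted p = 0.00617, and adjusted p = 0.286 with an estimated correlation). Cxcl2 changed by 2.21 ± 0.10 and Cxcl10 by -1.04 ± 0.23. Il10, an anti-inflammatory cytokine, changed by -0.49 ± 0.12. Gdf15, a stress-induced cytokine, went from 109 ± 18.6 to 932 ± 29.6 CPM (3.10 ± 0.12).

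Of 31 interferon response genes 30 fell with rHDL (30 adjusted over the list alone; adjusted p = 3.09e-10, and adjusted p = 0.268 with an estimated correlation), with a median of -0.74. Oas3 went from 1130 ± 139 to 549 ± 83.9 CPM (-1.04 ± 0.13), and Mx1 changed by -1.15 ± 0.14 on 15.6% of its exon bases. Ifnb1 was the member that did not pass (0.23 ± 0.37, adjusted p = 0.665). Of 20 NF-kB feedback and effector genes 10 fell and 3 (Icam1, Ptgs2 and Zc3h12a) rose (10 and 3 adjusted over the list alone; adjusted p = 0.0444, and adjusted p = 0.229 with an estimated correlation). Vcam1, an adhesion molecule, changed by -0.93 ± 0.10 and Nos2 by -0.45 ± 0.07. Of 14 inflammasome genes 8 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.00929, and adjusted p = 0.247 with an estimated correlation). Scaling by library totals ended the call of the NF-kB list. Tlr4, the LPS receptor, was at -0.20 ± 0.07 (adjusted p = 0.0409), and its call was lost without LPS replicate 1, 2 or 3 (adjusted p = 0.124, 0.102 and 0.0547), without rHDL replicate 1, 2 or 3 (0.0729, 0.0788 and 0.0946) and with library totals (0.483).

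H2-Aa, an MHC class II chain (chromosome 17, 34282751 to 34287771), went from 877 ± 111 to 108 ± 37.3 CPM with rHDL (-3.02 ± 0.22). Of 7 MHC class II genes 6 fell (7 adjusted over the list alone; adjusted p = 8.54e-06, and adjusted p = 0.209 with an estimated correlation), with a median of -2.09. Of 11 macrophage identity genes 9 fell and 1 (Cd68) rose (9 and 1 adjusted over the list alone; adjusted p = 2.01e-05, and adjusted p = 0.158 with an estimated correlation). C1qa, a complement component, changed by -2.38 ± 0.16, and Csf1r, the growth factor receptor of macrophages, by -0.83 ± 0.07. Of 14 costimulation and MHC class I genes 7 fell (8 adjusted over the list alone; adjusted p = 0.00771, and adjusted p = 0.364 with an estimated correlation), such as Cd86 (-1.63 ± 0.18). Beside these groups, the neutrophil markers S100a8 (-1.78 ± 0.22) and Mmp8 (-1.80 ± 0.23) were lower from under 8 CPM, as 2 of 2 measured (2 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.209 with an estimated correlation). Of 4 dendritic cell markers Bst2, also an interferon-induced gene, was lower (-0.56 ± 0.15) and Itgax was at 0.45 ± 0.20 (adjusted p = 0.0987). The platelet genes Pf4 (-0.59 ± 0.16) and Ppbp (-2.52 ± 0.42) were lower too, as 2 of 2 measured of the mast, erythroid and megakaryocyte list (2 adjusted over the list alone), which was not called (adjusted p = 0.0784) except with library totals. Of 4 stromal markers Vwf was higher, and the lymphoid marker measured did not pass.

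Of 18 unfolded protein response genes 11 rose with rHDL (11 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.209 with an estimated correlation), with a median of 0.34. Dnajb9, a chaperone of the endoplasmic reticulum, went from 21.7 ± 0.656 to 38.6 ± 5.21 CPM (0.83 ± 0.10). Of 19 oxidative stress genes of the NRF2 list 10 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 9.53e-05, and adjusted p = 0.058 with an estimated correlation), with Srxn1 at 1.48 ± 0.08. Of 22 lysosomal genes 12 rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.158 with an estimated correlation), with Mcoln1, a lysosomal calcium channel, at 0.87 ± 0.08. The ATF4 stress list (5 of 18 higher and 6 lower, and 5 and 7 adjusted over the list alone; adjusted p = 0.764) and the cytosolic heat shock list (3 of 13 higher and 3 lower, and 5 and 4 adjusted over the list alone; adjusted p = 0.517) were not called. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads are hard to assign, changed by -3.82 ± 0.20 and -3.40 ± 0.20. The control gene Actb changed by -1.004 ± 0.13, and by -1.02 with DESeq2 size factors and -0.89 with library totals.

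Of 8965 genes tested, rHDL raised 1621 and lowered 1654, and 4046 had an unadjusted p under 0.05. With a minimum of 1.5-fold the counts were 655 and 917. Scaling by library totals moved the median of all genes from 0.03 to 0.14 and gave 2507 higher and 1273 lower, so 66.3% of calls were higher in place of 49.5%. Of the 1538 LPS-induced genes 1497 were measured, and 708 fell and 187 rose (747 and 203 adjusted over the list alone), with a median of -0.30 (camera p = 1.78e-12, and p = 0.0436 with an estimated correlation). The LPS-repressed set had a median of 0.14 (p = 0.0177, and p = 0.38 with an estimated correlation). That call was lost without rHDL replicate 2 (median 0.0883).

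**Figure D1:**
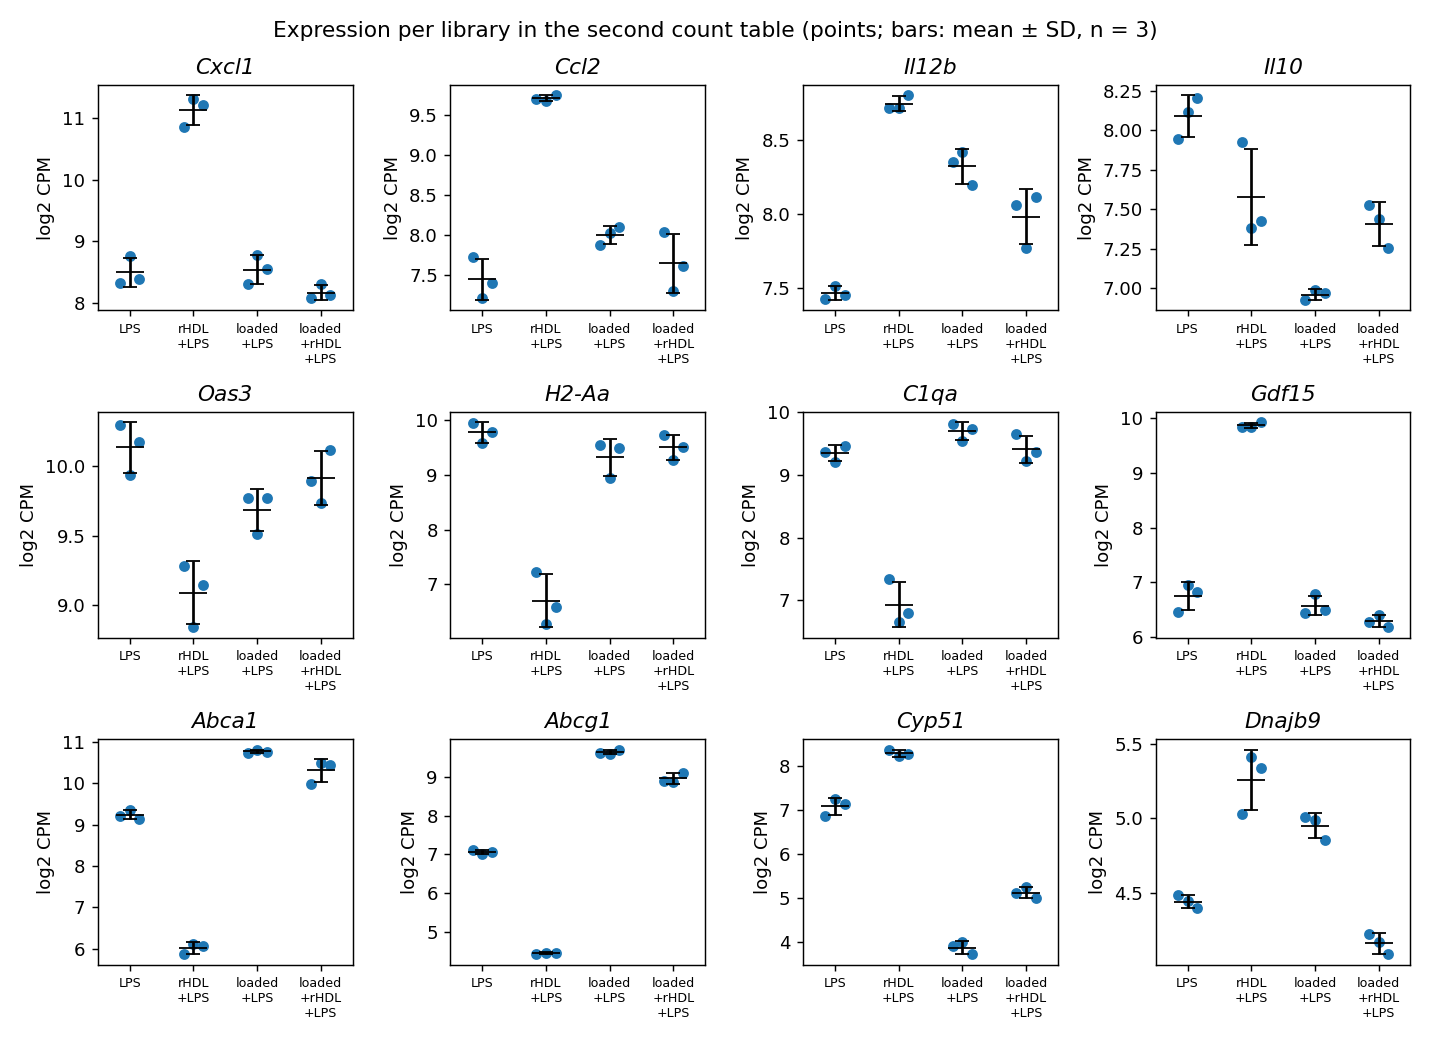
Log2 CPM (vertical axis) of 12 genes in the 4 LPS-stimulated groups of the second table (horizontal axis), with 1 point per library and bars for mean ± SD (n = 3). H2-Aa averaged 877 CPM with LPS, 108 after rHDL, 650 after loading and 730 after loading and rHDL.

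After cholesterol loading, rHDL addresses whether prior loading alters the lipoprotein's effect under LPS. Cyp51, an enzyme of sterol synthesis (chromosome 5, 4080674 to 4104697), went from 14.7 ± 1.48 to 34.9 ± 3.16 CPM, a log2 fold change of 1.24 ± 0.12 (adjusted p = 0.000103). Scd1 (chromosome 19, 44394450 to 44407709) went from 24.2 ± 1.79 to 2.40 ± 0.80 CPM (-3.32 ± 0.18, adjusted p = 2.61e-07), Scd2 changed by -2.04 ± 0.30, and Abcg1 went from 801 ± 32.8 to 501 ± 46.9 CPM (-0.68 ± 0.07). Abca1 was at -0.44 ± 0.11 and did not pass (adjusted p = 0.0944).

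Of 22 cholesterol synthesis genes 8 rose (10 adjusted over the list alone; adjusted p = 2.09e-09, and adjusted p = 0.0727 with an estimated correlation), with a median of 0.38. Hsd17b7 (1.12 ± 0.19) lost its call without loaded LPS replicate 3 (0.95, adjusted p = 0.0657). Of 14 LXR targets 6 fell (8 adjusted over the list alone; adjusted p = 2.04e-07, and adjusted p = 0.0107 with an estimated correlation, which held). Of 10 fatty acid synthesis genes Scd1 and Scd2, which are also LXR targets, fell (6 adjusted over the list alone; adjusted p = 3.18e-08, and adjusted p = 0.0292 with an estimated correlation, which held). The unfolded protein response list held too: 10 of 18 fell (11 adjusted over the list alone; adjusted p = 7.82e-15, and adjusted p = 0.0401 with an estimated correlation), with a median of -0.45. Dnajb9 went from 30.9 ± 1.74 to 17.9 ± 0.865 CPM (-0.79 ± 0.10), and Sdf2l1 changed by -0.72 ± 0.09 and Calr, a chaperone, by -0.45 ± 0.06. Hspa1a and Hspa1b, near-identical copies, changed by -1.87 ± 0.17 and -1.64 ± 0.18.

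Of 18 ATF4 stress genes 3 (Chac1, Slc7a5 and Trib3) rose (7 higher and 1 lower adjusted over the list alone; adjusted p = 1.67e-06, and adjusted p = 0.0571 with an estimated correlation). Their calls were lost without loaded LPS replicate 1 (adjusted p = 0.0777, 0.124 and 0.0759), 2 (0.0712, 0.170 and 0.105) or 3 (0.146, 0.225 and 0.0987). Leaving out a loaded rHDL library also ended calls: without replicate 1 Chac1 (adjusted p = 0.0531), without replicate 2 Chac1 (0.0557) and Slc7a5 (0.127), and without replicate 3 Slc7a5 (0.169) and Trib3 (0.0925). The call of Slc7a5 also ended with library totals (0.159).

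Inflammatory genes had no member called in the main edgeR fit after loading among 31 interferon response, 15 cytokine, 17 chemokine and 7 MHC class II genes. At an unadjusted p under 0.05 there were 3, 4, 2 and 0, and DESeq2 called 0, 3 (Il1a, Il1b and Il12b), 0 and 0. Cxcl1 was at -0.38 ± 0.14 (adjusted p = 0.283), Ccl2 at -0.33 ± 0.15 (adjusted p = 0.428), Il12b at -0.34 ± 0.09 (adjusted p = 0.0961) and H2-Aa at 0.17 ± 0.20 (adjusted p = 0.804). As a list, the interferon response was higher, with a median of 0.21 and 0 members higher adjusted over the list alone (adjusted p = 5.41e-05, and adjusted p = 0.477 with an estimated correlation). The inflammasome, anti-inflammatory regulator, NF-kB and costimulation and MHC class I lists were called higher too (adjusted p = 0.00105, 0.00174, 0.0117 and 0.00313). With an estimated correlation they were not (adjusted p = 0.179, 0.158, 0.162 and 0.363). Their medians were 0.16, 0.22, 0.09 and 0.19, and 1 anti-inflammatory regulator was called lower. The medians were 0.12 for cytokines (adjusted p = 0.171; 2 higher and 1 lower adjusted over the list alone), -0.01 for chemokines (adjusted p = 0.674) and 0.17 for MHC class II (adjusted p = 0.227). With the replicate number as a block the MHC class II list was called, though the labels do not pair equal numbers. Members called were not counted in that fit. The LPS-induced set had a median of 0.11 (camera p = 1.73e-11, and p = 0.0518 with an estimated correlation), with 20 of 1497 higher and 3 lower (32 and 4 adjusted over the list alone).

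Of 8965 genes tested after loading, rHDL raised 38 and lowered 53, and 1044 had an unadjusted p under 0.05. DESeq2 gave 94 and 83, or 53.1% higher in place of 41.8%, scaling by library totals gave 25 and 67, or 27.2% higher, and no low-count filter gave 90 and 86. The replicate number as a block, though the labels do not pair equal numbers, gave 277 and 209, or 57% higher. Leaving out 1 library moved the counts to 11 and 35, 10 and 20 or 13 and 22 without loaded LPS replicate 1, 2 or 3, and to 68 and 55, 20 and 35 or 28 and 28 without loaded rHDL replicate 1, 2 or 3.

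The difference between the rHDL effects was tested directly. Gdf15 (chromosome 8, 70629394 to 70631635) differed by -3.39 ± 0.17 on the log2 scale, loaded minus unloaded (adjusted p = 5.48e-08), with 109 and 932 CPM without loading. Abcg1 (chromosome 17, 31057694 to 31117981) differed by 1.94 ± 0.11, Abca1 by 2.77 ± 0.17 and Cxcl2 by -2.44 ± 0.14. Of 31 interferon response genes 29 had a higher effect after loading (30 adjusted over the list alone; adjusted p = 5.21e-11, and adjusted p = 0.243 with an estimated correlation). The same held for 6 of 7 MHC class II genes (6 adjusted over the list alone; adjusted p = 9.3e-06, and adjusted p = 0.217 with an estimated correlation) and 9 of 11 macrophage identity genes (9 adjusted over the list alone; adjusted p = 3.82e-05, and adjusted p = 0.153 with an estimated correlation). The effect was lower for 12 of 18 unfolded protein response genes (13 adjusted over the list alone; adjusted p = 5.46e-08, and adjusted p = 0.125 with an estimated correlation) and 10 of 22 cholesterol synthesis genes (10 adjusted over the list alone; adjusted p = 3.42e-05, and adjusted p = 0.173 with an estimated correlation).

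In all, 1432 genes had a higher and 1272 a lower rHDL effect after loading, and 3584 had an unadjusted p under 0.05. Of the 3275 genes called without loading, 2394 differed. Across the 8965 genes, which are not independent replicates, Pearson's r between the rHDL effects was -0.148 and Spearman's rho -0.233. Of 61 genes called in both, 28 moved the same way and 33 opposite ways. Those moving the same way were 14 higher (6.87 expected from independent lists) and 14 lower (9.78 expected). No expectation was computed for opposite ways. Scaling by library totals gave 1016 and 2124, or 32.4% higher in place of 53.0%, and moved the median of all genes from -0.03 to -0.20. Leaving out 1 library moved r to between -0.228 (without loaded rHDL replicate 2) and -0.06 (without loaded LPS replicate 2). The jackknife SD of r over the libraries was 0.16, larger than r in size, so no inverse relation is concluded.

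**Figure D2:**
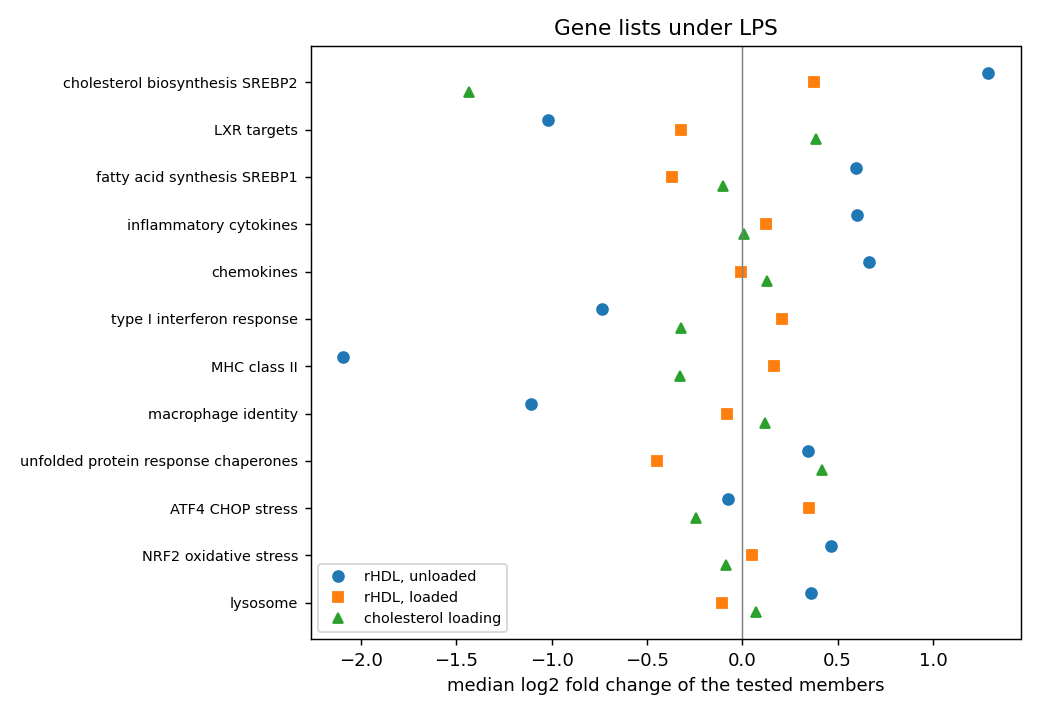
Median log2 fold change (horizontal axis) of the measured members of 12 fixed lists (vertical axis) for rHDL without loading, rHDL after loading, and loading itself, all under LPS. The unfolded protein response list lies at 0.34 for rHDL without loading, -0.45 for rHDL after loading and 0.42 for loading.

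Cholesterol loading against none, under LPS and without rHDL, gives the effect of the liposomes as a whole. No group had liposomes without cholesterol, so cholesterol cannot be told from the phosphatidylcholine given with it. Cyp51 went from 136 ± 17.5 to 14.7 ± 1.48 CPM (-3.20 ± 0.11, adjusted p = 3.17e-10), and Sc5d (-2.93 ± 0.13) and Idi1 (-3.37 ± 0.22), enzymes of sterol synthesis, fell with it. Abcg1 went from 133 ± 5.48 to 801 ± 32.8 CPM (2.58 ± 0.07, adjusted p = 4.7e-11) and Abca1 from 603 ± 46.8 to 1743 ± 49.4 (1.53 ± 0.12). Of 22 cholesterol synthesis genes 15 fell (18 adjusted over the list alone; adjusted p = 2.83e-27, and adjusted p = 0.00818 with an estimated correlation, which held), with a median of -1.43. Of 14 LXR targets 7 rose (8 adjusted over the list alone; adjusted p = 1.41e-06, and adjusted p = 0.00818 with an estimated correlation, which held), among them Scd1 (3.13 ± 0.18) and Mylip (1.89 ± 0.08).

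Of 18 unfolded protein response genes 11 rose with loading (14 adjusted over the list alone; adjusted p = 1.58e-10, and adjusted p = 0.0891 with an estimated correlation), such as Sdf2l1 (0.87 ± 0.09) and Pdia6 (0.55 ± 0.07). Of 17 chemokines 6 rose (6 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.452 with an estimated correlation), with Ccl22 at 1.36 ± 0.12 and Cx3cl1 at 1.17 ± 0.11. Il12b rose by 0.86 ± 0.09, while Il10 went from 273 ± 24.9 to 125 ± 2.75 CPM (-1.13 ± 0.13). Il10 was 1 of 5 anti-inflammatory regulators of 15 that fell (8 adjusted over the list alone; adjusted p = 0.000135, and adjusted p = 0.115 with an estimated correlation). Of 31 interferon response genes 4 fell (6 adjusted over the list alone; adjusted p = 1.93e-07, and adjusted p = 0.452 with an estimated correlation), with Oas2 at -0.50 ± 0.10. Of 17 glycolysis and hypoxia genes 7 fell (10 adjusted over the list alone; adjusted p = 1.72e-05, and adjusted p = 0.255 with an estimated correlation), such as Hk2, a hexokinase (-0.62 ± 0.06), and Hif1a (-0.43 ± 0.07).

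Some panel genes passed with loading by a small margin. Ccl2 rose by 0.55 ± 0.15 (adjusted p = 0.0402). Its adjusted p passed the threshold no longer without LPS replicate 2 (0.43, adjusted p = 0.136) or 3 (0.52, 0.132), or loaded LPS replicate 1 (0.61, 0.061), 2 (0.53, 0.11) or 3 (0.50, 0.143), though the change kept its direction. Nos2 changed by -0.31 ± 0.07 (adjusted p = 0.0196), and its call was lost without LPS replicate 1 (-0.24, adjusted p = 0.0996) or loaded LPS replicate 1 (-0.32, 0.0547) or 3 (-0.26, 0.114), and with library totals (-0.22, 0.0579). The neutrophil marker S100a8 was at -0.92 ± 0.21 (adjusted p = 0.0152), and its call was lost without LPS replicate 1 (-0.91, adjusted p = 0.0547) or 3 (-0.91, 0.054) or loaded LPS replicate 1 (-0.91, 0.0548) or 3 (-0.87, 0.0699). Il6 was at -0.12 ± 0.19 (adjusted p = 0.766) and H2-Aa at -0.43 ± 0.20 (adjusted p = 0.216).

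Of 8965 genes tested, loading raised 358 and lowered 410, and 2128 had an unadjusted p under 0.05. Without LPS replicate 1 or 3 the counts were 158 and 207 or 169 and 212, and without loaded LPS replicate 1, 2 or 3 they were 234 and 243, 178 and 218 or 161 and 189. Scaling by library totals gave 626 and 254, or 71.1% higher in place of 46.6%. A minimum of 1.5-fold gave 115 and 141, and a fit of the 2 groups alone 525 and 691. The LPS-induced set had a median of -0.13, with 198 of 1497 lower and 63 higher (270 and 79 adjusted over the list alone; camera p = 1.71e-09, and p = 0.0751 with an estimated correlation).

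**Figure D3:**
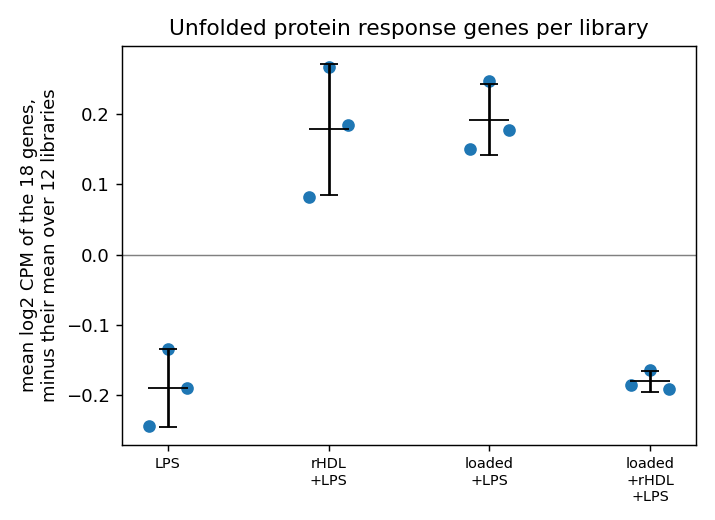
Mean log2 CPM of the 18 measured unfolded protein response genes in each library, minus their mean over the 12 libraries of the second table (vertical axis), by group (horizontal axis). Points are libraries and bars mean ± SD (n = 3), and the 3 libraries with loading alone lie between 0.15 and 0.248 while those with loading and rHDL lie between -0.192 and -0.164.

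The deposited comparison tables list 1609 rows for rHDL without loading, 830 higher and 779 lower, and 47 after loading, 17 higher and 30 lower. Of the 1556 rows without loading whose gene was tested here, 1537 (98.8%) were called in the same direction and 1 in the opposite direction. After loading it was 39 of 47 in the same direction and 0 in the opposite, and DESeq2 called 43 of the 47 in the same direction. The tables were made from these libraries and are not independent evidence.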

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

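Tests on the 3 patterns weighed here were chosen after the results were seen, while the counts over other splits of the libraries were planned. The results below were singled out because the effect of rHDL under LPS differed with cholesterol loading in a test of the difference itself. It was higher after loading for 1432 genes and lower for 1272, and 14 of the fixed lists differed with the preset correlation and 0 with an estimated one. The LPS-induced set had a median difference of 0.419. Of 100 splits of the 12 libraries, 1 (the real one) gave as many genes as 2704, and the highest other gave 1748. For the lists, 2 of the 100 splits gave as many as 14, and the highest other gave 14. A split that mixes the 4 groups also adds the effects of rHDL and of loading to the spread within groups. These splits therefore cannot single out a difference between rHDL effects, and no conclusion on chance is drawn for either count.

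Of 88 named genes of the rHDL comparisons, 77 had such a difference, against 30.2% of all 8965 genes tested. Named genes were picked partly by their values in these comparisons, so their higher share is no separate result. The difference contains the unloaded effect with its sign reversed, so its direction is no separate result either. Log2 differences, loaded minus unloaded, for inflammatory genes were Il12b -1.63, Ccl2 -2.59, Ptgs2 -0.45, Csf2 -3.99, Gdf15 -3.39, Cxcl1 -3.01, Il23a -2.2, Osm -1.63, Cxcl2 -2.44, Icam1 -0.52 and Tlr13 -0.77. They were positive for Cxcl10 (1.32), Nos2 (0.41), Il10 (0.94), Tlr4 (0.42), Vcam1 (1.07), Mx1 (1.21), Oas3 (1.28), Tlr8 (0.9), Tlr3 (1.33), Aim2 (0.87), Il18bp (2.0), Rsad2 (1.09) and Mmp13 (2.03). For lipid genes they were Abca1 2.77, Abcg1 1.94, Insig1 -1.36, Sqle -0.72, Pltp 1.19, Mylip 1.11, Fads2 -4.56, Fasn -1.99, Ch25h 1.49, Plin2 -0.47, Scd1 -4.01 and Scd2 -2.13. Fads2 averaged 0.386 CPM with loading and 0.118 with loading and rHDL, so the size of its difference rests on few counts. For stress and lysosomal genes the differences were Creld2 -1.08, Dnajb9 -1.62, Hyou1 -1.25, Sdf2l1 -1.28, Dnajc3 -1.02, Calr -0.85, Slc7a11 -0.81, Nupr1 1.76, Trib3 0.67, Chac1 1.07, Slc7a5 0.79, Srxn1 -1.43, Gclm -1.2, Hmox1 -0.54, Atp6v0d1 -0.89, Mcoln1 -0.98, Hspa1a 1.95 and Hspa1b 1.75. For antigen presentation, identity and marker genes they were H2-Eb1 3.45, H2-Aa 3.19, H2-Ab1 2.66, Cd74 2.23, Cd86 1.82, C1qa 2.1, C1qb 1.78, Csf1r 0.88, S100a8 1.65, Mmp8 1.12, Itgax -0.85, Bst2 0.77, Pf4 0.75 and Ppbp 3.3. The remaining values were Actb 1.17, Il4ra 1.61, Col4a1 1.62, Aph1c -1.42, Cbr2 1.03, Plxna2 -2.29, Selp 4.08, U90926 4.68 and Gda 1.71.

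rHDL changed 3275 genes without loading and 91 after it, a ratio of 36. The ratio was lowest, at 8.3, with the replicate number as a block, though the labels do not pair equal numbers. DESeq2 lowered it to 17.7. Fits of the 2 groups alone raised it to 81, with 3404 calls without loading and 42 after it. The 91 therefore depends on the fit shared by all 12 libraries. The 91 became 46, 30 or 35 without loaded LPS replicate 1, 2 or 3. Without loaded rHDL replicate 1, 2 or 3 it became 123, 55 or 56. Depth is argued against as the whole cause, since counts thinned to the smallest library gave a ratio of 40.4. Reads dropped between overlapping rows are argued against by the ratio of 32.8 among genes with 1 row and no shared exon base. A larger spread among loaded libraries (median SD of log2 CPM 0.163, against 0.136) would leave the effects themselves alike, but the slope of the loaded on the unloaded effects over the called genes was -0.062 (-0.114 to -0.021 leaving out 1 library). An effect of loading on the response to rHDL may therefore be proposed, as a hypothesis found and tested on the same data.

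With rHDL and no loading 6 of 7 MHC class II and 9 of 11 macrophage identity genes fell, with a median of -1.66 over the 18 members, and both list calls were lost with an estimated correlation (adjusted p = 0.209 and adjusted p = 0.158). Scaling is argued against, since library totals alone gave -1.551, with 16 of the 18 lower. Fewer dendritic cells among the cultures cannot be told apart from a change within macrophages for the MHC class II genes, because 1 of 4 dendritic markers was lower: Bst2, at a mean log2 CPM of 8.56, also answers to interferon. Itgax, at 6.57 and also expressed by macrophages, was at 0.45 ± 0.20, Xcr1 and Ccr7 had under 2 CPM on average, and 2 of 2 neutrophil markers and 2 of 2 genes of the mast, erythroid and megakaryocyte list fell too. A change within the macrophages and a loss of other cells stay open.

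Of 18 unfolded protein response genes 11 rose with rHDL without loading (adjusted p = 0.209 with an estimated correlation, so the list call was lost) and 10 fell with it after loading (adjusted p = 0.0401, which held). A deviating library is argued against: leaving out each in turn kept the loaded median between -0.452 and -0.407 and the unloaded one between 0.283 and 0.400. Scaling is argued against by -0.506 after loading and 0.462 without it under library totals. Per library, the members lay from -0.245 to -0.134 with LPS, 0.082 to 0.268 with rHDL, 0.15 to 0.248 with loading, and -0.192 to -0.164 with both. Loading itself raised these genes (median 0.42), and the libraries with both lay within the range of LPS alone. The fall after loading, measured against the loaded LPS libraries, may thus be a return from that rise. These groups cannot tell it from an opposite response of these genes after a cholesterol load. Either may be proposed only as a hypothesis found on the same data. The list call of the difference was lost with an estimated correlation (adjusted p = 0.125).

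With 3 libraries against 3 there are 10 splits, so no share under 0.1 can be reached for the other comparisons. Each split other than the real one mixes the groups compared. That adds their difference to the spread within groups and leaves part of it between them. The values of other splits therefore do not show what would arise without an effect, and no conclusion on chance is drawn. For LPS, 1 split gave as many genes as the real 6985 and the highest other gave 0, and for its lists 2 splits gave 14 and the highest other 14. For rHDL without loading it was 1 split, 3275 genes and 0, and for its lists 1 split, 15 and 12. The LPS-induced median under rHDL was -0.296 (1 split; highest other 0.181 in size) and the LPS-repressed one 0.139 (2 splits; highest other -0.143). For rHDL after loading it was 1 split, 91 genes and 0, for its lists 1 split, 13 and 7, and for the LPS-induced median 2 splits, 0.107 and 0.108. For loading it was 1 split, 768 genes and 1, for its lists 1 split, 14 and 7, and for the LPS-induced median 1 split, -0.13 and 0.109.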

How the results depend on the processing

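Scaling by library totals, rows tested singly, genes with 1 row and no shared exon base, and thinned counts were chosen after seeing the data, and the others were fixed in advance. Causes were not tested unless stated. A minimum of 1.5-fold, which by construction calls fewer genes, gave 655 higher and 917 lower for rHDL, 16 and 25 for rHDL after loading, 723 lower for the difference, and 115 and 141 for loading. Library totals gave 1532 and 6640 for LPS, 2507 higher for rHDL, 25 higher for rHDL after loading, 2124 lower for the difference, and 626 and 254 for loading, and the signs of Abca1 (-0.153) and Atf3 (-0.134) with LPS reversed. For rHDL after loading, no low-count filter gave 90 and 86, DESeq2 94 and 83, and the 2 groups alone 19 and 23. In such fits rHDL without loading gave 1649 and 1755 and loading 525 and 691, so not every count fell. With the replicate number as a block, rHDL after loading gave 277 and 209, loading 717 and 934 and rHDL without loading 2036 and 1974, so the ratio of calls without to after loading fell from 36 to 8.3. The block added a call of the MHC class II list for rHDL after loading, and for the difference ended that of the chemokine list and added the mast, erythroid and megakaryocyte list. The labels do not say that equal numbers belong together: 13 of 18 pairs of equal number correlated above 0.1 in the second table (-0.03 to 0.436) and 0 of 3 in the first (-0.077 to 0.074), and 10 of 12 and 1 of 6 libraries correlated best with their own number, a hint from the data and not the design. Leaving out each library gave 10 to 68 higher and 20 to 55 lower for rHDL after loading, and 158 to 245 higher and 189 to 349 lower for loading. The LPS-repressed median under rHDL ran from 0.0883 to 0.182, and the call was lost at the former, without rHDL replicate 2, and for the genes with the largest change alone (0.244). With an estimated correlation the medians of 0.107 (LPS-induced, rHDL after loading), 0.139 (LPS-repressed, rHDL) and -0.13 (LPS-induced, loading) were past the threshold no longer. It called 0 fixed lists in place of 14 for LPS, 1 of 15 for rHDL, 3 of 13 after loading, 0 of 14 for the difference and 2 of 14 for loading. Over 3050 alternatives of 206 named gene results, 71 lost their call, 46 gained one and 2 reversed. At this depth 38 to 75 of 100 simulated changes of 1.5-fold were recovered, depending on the comparison, against 72 to 85 at 2-fold. The simulations changed few genes, drew genes independently and gave all groups the same spread for a gene. They therefore do not give the recovery in comparisons with many changed genes, such as LPS, or in groups with a larger spread.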

Other observations

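The 2 LPS groups of the separate tables, each scaled within its own table and not tested against the other, differ in level. Il10 was at 14.3 ± 4.49 CPM (SD, n = 3) in the first table and 273 ± 24.9 in the second. Csf2 was at 123 ± 18.6 and 2.40 ± 0.988, and Il23a at 63.4 ± 10.7 and 5.54 ± 0.418. Cxcl2 was at 13970 ± 256 and 1516 ± 204, and Mki67 at 496 ± 79.3 and 158 ± 28.1.

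A hypothesis, with a test chosen after the result was seen, is that rHDL after loading may reverse part of the effect of loading. These comparisons share the loaded LPS libraries, so an opposite relation arises without any effect, and 20 simulations of unchanged groups gave its size. The covariance of the log2 effects was -0.0458, against -0.0203 on average and -0.0215 at the lowest in the simulations, a difference of -0.0255. Leaving out 1 library gave -0.0724 to -0.0448. The correlation was -0.517, against -0.496, and 69.5% of genes were opposite in sign, against 66.5%. Genes called higher by loading and lower by rHDL after it numbered 34 (2.12 expected from independent lists), those lower and then higher 24 (1.74 expected), and those in the same direction 2 (3.94 expected). That expectation leaves out the shared libraries, and the simulations, in which 0 genes were called in both in opposite directions, leave out the effects, so the excess over either is not taken as support. Scd1 rose by 3.13 ± 0.18 with loading and changed by -3.32 ± 0.18 with rHDL after it. The simulations hold no deviations shared among genes, so part of the excess may come from the shared libraries.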
